A study of Arabidopsis thaliana with 17 samples.

How the data were processed

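The series holds 17 samples of Arabidopsis thaliana, all from 14-day-old plants: 11 RNA-seq libraries of whole roots, and 6 libraries of RNA or chromatin recovered with an HA-tagged NF-YA2 from seedlings, with their inputs. NF-YA2 is a subunit of the NF-Y transcription factor, which binds the CCAAT box, and BAMBOO is a long non-coding RNA (lncRNA). The comparison made here was between roots of bamboo (2 libraries, numbered 2 and 3 in the labels) and the wild-type set Col-0-b (3 libraries). The submitters' design calls bamboo a mutant, while the name of its deposited table carries KD, a usual short form of knock-down; how BAMBOO was changed is not given in the sources used here. A second wild-type set, Col-0 (3 libraries), came with a table holding raw counts. The libraries of the HA-NF-YA2 line and the 6 immunoprecipitation and input libraries were not analysed here.

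Per the labels, libraries were made with a stranded Illumina mRNA kit and read as single ends. Per the submitters' processing notes, Trimmomatic, STAR 2.7.2a and featureCounts of Subread 1.6.5 were used with the build TAIR10; which strand setting the counting used is not given in the sources used here, so a gene and an antisense partner may share reads. The authors deposited raw counts per gene for Col-0, with 13637179 to 21206367 reads a library. For bamboo and Col-0-b the authors deposited a signal, gene counts divided by a size factor for each library. How those size factors were made is not given in the sources used here. In each of the 5 columns every value was a whole multiple of a step within a tolerance of 0.01 (100% of values), so reads could be recovered: 16963843 to 24333119 a library, with size factors from 0.811 to 1.18. In Col-0-b replicate 1 the step was 0.9994, so near 1 that low values were almost whole numbers, while higher ones were not (567.7 for NF-YA2). The columns named WT were taken as Col-0-b because that set is the wild type paired with bamboo; the names themselves say only wild type.

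The raw-count table also held 6 columns whose names do not say which line they are. None of their values enters a result. One of the 2 names was first taken provisionally as the HA-NF-YA2 line, and the counts of NF-YA2 and NF-YA10 were looked at under that reading. NF-YA2 was not higher there than in Col-0, and the reading was withdrawn on seeing this, so that leaving the line out depended on values. The names do not settle it either, and the other name was not assigned from values. The comparison of the HA-NF-YA2 line with Col-0, the overlap of its genes with those of bamboo and the test of its genes as sets in bamboo were therefore not made, although they had been chosen before the data were examined.

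Values were compared as log2(normalized count + 1). Genes with a normalized count of at least 10 in at least 2 libraries were tested (20274 of 37336 features) with limma 3.58.1 in R 4.3.3, using the trended and robust moderated test with group as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are bamboo minus Col-0-b on this scale, which understates the change of low genes. The standard error (SE) stands beside the fold changes of the genes described first, those of other genes and list members are given without it, and levels are mean ± SD. Gene lists were fixed before the data were examined (20 lists, 19 with at least 5 tested members) and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists. Members passing singly were counted over all genes and adjusted over the list alone. Symbols came from a RefSeq gene table of the assembly TAIR10.1, which held 37051 of the 37336 features. It was used for names, gene classes and neighbours, and none of its coordinates are given because its build differs from that of the files. It has no entry named BAMBOO, and the level of BAMBOO was not analysed here.

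The rule for named genes, also fixed before the data were examined, took NF-YA2 and its paralogue NF-YA10, the 8 largest changes in each direction among called genes with non-overlapping libraries and a mean above the median of tested genes, and up to 2 called members of each list. Every other called gene, and every list member that was not called, was named after its values were seen. The value of 1 list member is not reported here. Other settings chosen before the data were examined were a pseudocount of 8, no low-value filter, TMM-rescaled values, edgeR 4.0.16 quasi-likelihood on the recovered reads, a replicate term, a log2 fold change of at least 1, an estimated inter-gene correlation, and leaving out each library in turn. DESeq2 1.42.0 on the recovered reads was added after seeing the data.

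The test was tried on simulated counts of 20300 genes with 200 changed, made from these libraries' means and depths: it recovered 65.1% of 1.5-fold, 88.5% of 2-fold and 97.6% of 4-fold changes, and 8.4% of its calls were false, above the nominal 5%. Simulated libraries all shared the same spread for a gene and none was made to stand apart, so these shares need not hold for the real libraries. The list test recovered 20 of 20 lists shifted 1.3-fold and called 0 of 380 unshifted lists. The simulated genes varied independently of each other, so this trial cannot show how often the list test errs when genes are correlated. No pair of replicates came near sampling noise (chi-square per degree of freedom 5.8 to 22.78), so none was counted as a duplicate. The labels do not say whether replicates were separate cultures, and p-values measure only the spread between these samples. A count of 0 was set against a floor of 3 reads over the group's libraries, which covers counting error only.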

Results

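Whole-root transcriptomes of bamboo (n = 2) were set against those of the wild-type Col-0-b (n = 3), all from 14-day-old plants, to ask which transcripts differ when the lncRNA BAMBOO is affected. Depth ran from 16963843 reads in Col-0-b replicate 2 to 24333119 in bamboo replicate 3. The first principal component of the log2 values held 44.7% of the variance. Bamboo replicate 2 lay at 34.7 on it, bamboo replicate 3 at 6.5 and the 3 Col-0-b libraries at -8.6, -10.8 and -21.9. Bamboo replicate 3 had a correlation of 0.9904 with bamboo replicate 2. Its correlations with Col-0-b replicates 1, 2 and 3 were 0.9924, 0.9914 and 0.9902, so its closest match was Col-0-b replicate 1. Bamboo replicate 2 had correlations of 0.9872, 0.9861 and 0.9834 with the same libraries, so its closest match was bamboo replicate 3.

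NF-YA2, the transcription factor subunit named with BAMBOO in the study's title, had nearly equal levels in both genotypes, at 541 ± 9.45 normalized counts in bamboo (SD, n = 2) and 550 ± 35.1 in Col-0-b (SD, n = 3). Its log2 fold change was -0.02 (SE 0.09, limma adjusted p = 0.936). Its paralogue NF-YA10 had a log2 fold change of 0.17 (SE 0.16, adjusted p = 0.616). Neither difference exceeded the spread between libraries.

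In bamboo roots, 14 genes were higher and 13 were lower than in Col-0-b, and 10 of the 27 changed at least 2-fold. Among transcripts that rose, NRT2.6, a member of the high-affinity nitrate transporter family, went from 7.5 ± 0.457 normalized counts to 95.5 ± 28.4, a log2 fold change of 3.48 (SE 0.31, limma adjusted p = 0.000696). CBL8, a calcineurin B-like calcium sensor, rose by 1.77 (SE 0.28, adjusted p = 0.0311) and the lncRNA AT3G05945 by 1.67 (SE 0.18, adjusted p = 0.00409). Among those that fell, AT5G35760 went from 311 ± 21.5 to 30.2 ± 0.48, a log2 fold change of -3.32 (SE 0.14, adjusted p = 4.5e-07). ARP9, an actin-related protein, went from 912 ± 95.6 to 342 ± 45.4, a log2 fold change of -1.42 (SE 0.11, adjusted p = 0.000224).

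Some of the called genes were chromosomal neighbours. AT3G13276 had 0 reads in both bamboo libraries, against 27 to 30 reads in each Col-0-b library. Against a floor of 3 reads over the 47089081 bamboo reads, it was at least 23.1-fold lower. The adjacent non-coding RNA AT3G13277 fell from 195 ± 13.4 to 93.7 ± 12.5 (log2 fold change -1.05, SE 0.14, limma adjusted p = 0.0157). The other wild-type set, Col-0, came with a separate table of raw counts and was not tested here. In it AT3G13276 was also low, at 0 to 0.189 CPM (read counts scaled to library size), against a mean of 1.47 CPM in Col-0-b. AT3G13277 had a mean of 2.8 CPM in Col-0 (1.98 to 3.63), below its means of 4.49 CPM in bamboo and 9.38 CPM in Col-0-b. The pseudogene AT5G35935 rose from 79.3 ± 29.2 to 668 ± 14.6 (log2 fold change 3.14, SE 0.33, adjusted p = 0.0425), while the adjacent gene AT5G35940 fell from 1160 ± 225 to 429 ± 23.2 (log2 fold change -1.42, SE 0.13, adjusted p = 0.00409). The summed level of AT5G35935 and AT5G35940 differed by -0.17 (SE 0.11) and the separate values of the 2 are uncertain where the authors' counting could split reads between them. The pseudogene AT3G29120 rose by 1.26 (SE 0.18, adjusted p = 0.0203).

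The other 17 called genes changed less than 2-fold. HSP90.1, a heat-inducible chaperone, rose from 1990 ± 230 to 3050 ± 167, and MBF1C, a transcriptional coactivator of the heat response, from 503 ± 13.8 to 832 ± 155. CKX4, a cytokinin-degrading oxidase, rose from 539 ± 47 to 848 ± 45.1, and MBD10, a methyl-CpG-binding domain protein, from 868 ± 50.2 to 1350 ± 74.4. AT3G24100 (log2 fold change 0.76), AT2G28720 (0.60), AT5G04750 (0.57), AT2G36690 (0.92) and AT1G56660 (0.83) were also higher. SUC2, the sucrose transporter of phloem loading, fell from 2010 ± 140 to 1390 ± 46.4, and SUS1, a sucrose synthase, from 1050 ± 62.2 to 701 ± 50.1. FRD3, a citrate transporter needed for iron transport in the xylem, had a log2 fold change of -0.46, OCT1, an organic cation transporter, of -0.74, and the expansin EXPA14 of -0.61. AT1G49470 (-0.60), AT5G15950 (-0.59) and AT2G47560 (-0.68) were lower as well. Adjusted p-values of these 17 genes lay between 0.0108 and 0.0372 (limma).

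**Figure D1:**
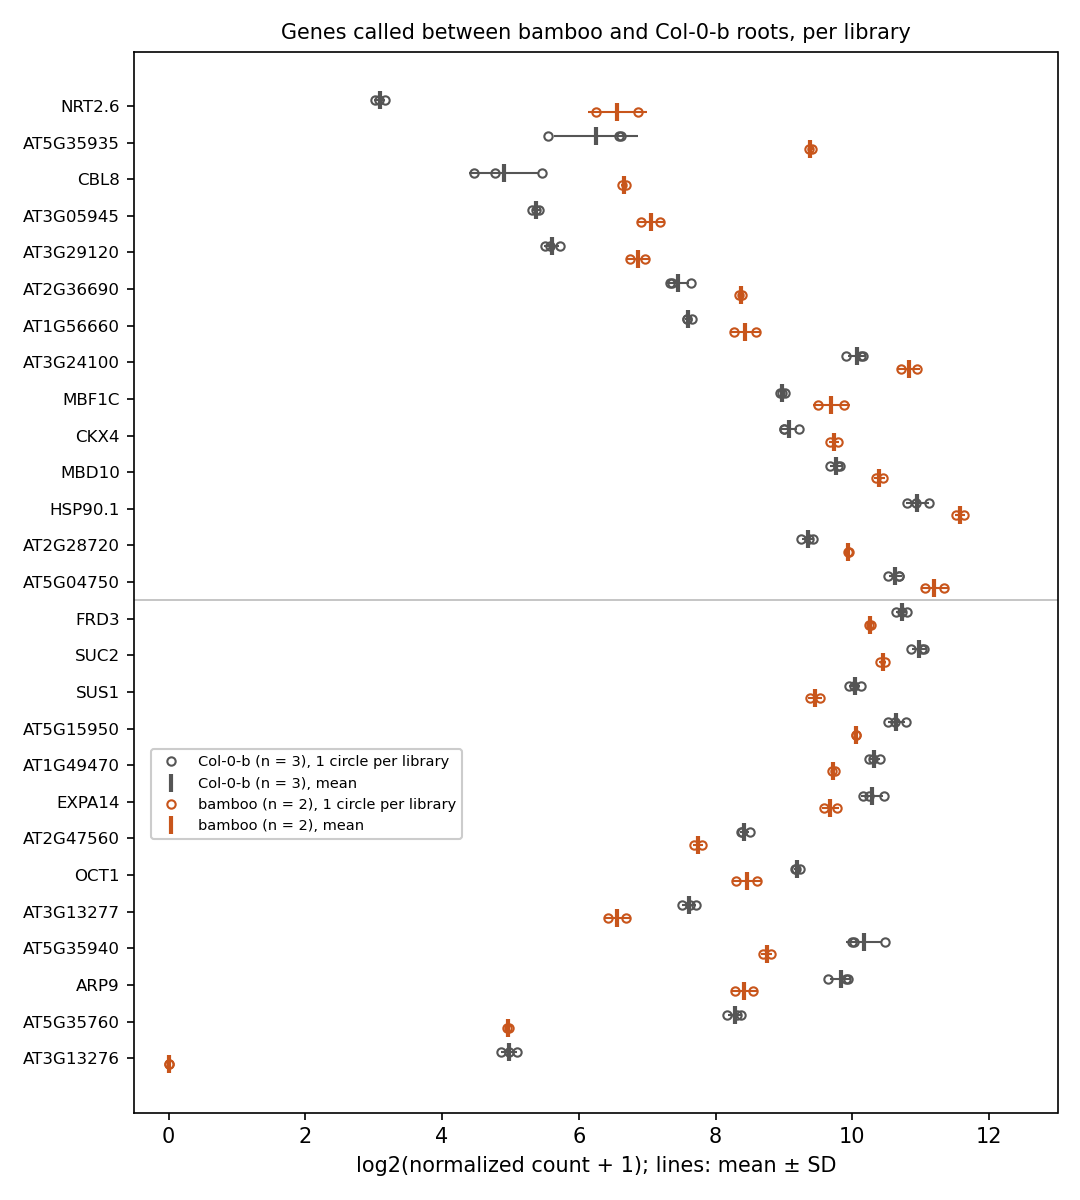
Log2(normalized count + 1) of the 27 called genes on the x axis, 1 circle per library for bamboo (orange, n = 2) and Col-0-b (grey, n = 3), with the mean as a vertical tick and the SD as a line. Genes are ordered by fold change from NRT2.6 (3.48) at the top to AT3G13276 (0 reads in bamboo) at the bottom, and the libraries of the 2 genotypes do not overlap for any of them.

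All 27 called genes had non-overlapping libraries, which chance gives for 20% of genes and which 34.6% of all tested genes showed; 3407 genes had an unadjusted p under 0.05, where 1014 would be expected by chance. On the recovered reads, edgeR called 15 genes higher and 13 lower, and DESeq2, added after seeing the data, 182 and 135. Leaving out 1 library at a time gave 6 higher and 4 lower without Col-0-b replicate 1, 26 and 13 without its replicate 2, 7 and 5 without its replicate 3, 13 and 18 without bamboo replicate 2, and 894 and 1052 without bamboo replicate 3. ARP9, AT3G13276, AT3G05945, NRT2.6 and AT5G35760 kept their call in each alternative that gave them an adjusted p, and the other 22 genes lost it in at least 1. NRT2.6 was given one in 8 of 11 alternatives; without either bamboo library it was not tested, since it reached the minimum level only in those 2 libraries.

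Genes of the cytokinin response were higher in bamboo as a list: 11 of its 12 tested members had a positive fold change, with a median of 0.25 (camera adjusted p = 1.48e-05; adjusted p = 0.382 with an estimated correlation). CKX4 was the member called over all genes, and 7 were called when adjusted over the list alone. These included the type-A response regulators ARR7 (log2 fold change 0.34), ARR6 (0.32), RR5 (0.41) and RR3 (0.37), which dampen cytokinin signalling. The list had a median of 0.31 in bamboo replicate 2 and 0.24 in bamboo replicate 3, and its call held without either.

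The heat shock list was higher in 7 of 7 tested members, with a median of 0.37 (camera adjusted p = 1.6e-05; adjusted p = 0.382 with an estimated correlation). HSP90.1 and MBF1C were called over all genes, and HSP70 (0.33) and HSP101 (0.23) joined them when adjusted over the list alone, 4 in all. The small heat shock proteins HSP17.6A and HSP18.2 had values of 0.94 and 0.37 and were not called.

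Auxin synthesis and transport genes were lower in 16 of 17 tested members, with a median of -0.20 (camera adjusted p = 1.94e-05; adjusted p = 0.489 with an estimated correlation). None was called over all genes and 5 were called as lower when adjusted over the list alone. They included the auxin efflux carriers PIN3 (-0.30), PIN7 (-0.29) and EIR1, also known as PIN2 (-0.58), and the auxin-synthesis enzyme YUC6 (-0.27). The median was -0.21 in bamboo replicate 2 and -0.22 in bamboo replicate 3. The auxin response list did not pass (14 of 18 higher, median 0.12, adjusted p = 0.0641), and its adjusted p ran from 0.0259 without Col-0-b replicate 3 to 0.214 without Col-0-b replicate 2.

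Nitrogen uptake and assimilation genes were higher in 7 of 7 tested members, with a median of 0.17 (camera adjusted p = 0.0134; adjusted p = 0.382 with an estimated correlation). The nitrate transporter NRT2:1 had a value of 0.50, the nitrate reductase NIA1 0.44 (SE 0.42) and the nitrite reductase NIR1 0.19. None of the 7 was called singly, over all genes or when adjusted over the list alone.

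Endodermal barrier genes were higher in 14 of 15 tested members (median 0.15, camera adjusted p = 0.00247; adjusted p = 0.523 with an estimated correlation), with values of 0.30 for MYB36, a regulator of Casparian strip formation, and 0.28 for PER64. Root hair genes were higher in 12 of 16 (median 0.26, adjusted p = 0.039; adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone, 4 root hair genes were called as higher, among them RHS19 (0.50) and COW1 (0.37), and 2 as lower, RHD6 (-0.38) and LRX2 (-0.49). Circadian clock genes were higher in 10 of 12 (median 0.14, adjusted p = 0.024; adjusted p = 0.489 with an estimated correlation), with PRR5 at 0.36. Mitotic cell cycle genes were lower in 16 of 20 (median -0.16, adjusted p = 0.00588; adjusted p = 0.523 with an estimated correlation), with the cyclins CYCB1;1 at -0.34 and CYCA2;4 at -0.33. No member of the endodermal, clock or mitotic lists was called singly. Bamboo replicate 2, which stood apart on the first principal component, carried more of the endodermal, root hair and mitotic shifts (medians 0.23, 0.27 and -0.20) than bamboo replicate 3 (0.05, 0.09 and -0.08). The clock shift was alike in both, with medians of 0.15 and 0.16. Without bamboo replicate 2 the adjusted p was 0.324 for the endodermal, 0.199 for the root hair, 0.0552 for the clock, whose median was then 0.16, and 0.128 for the mitotic list. The root hair call was also lost without Col-0-b replicate 1 (0.199) and the clock call without Col-0-b replicate 2 (0.102).

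**Figure D2:**
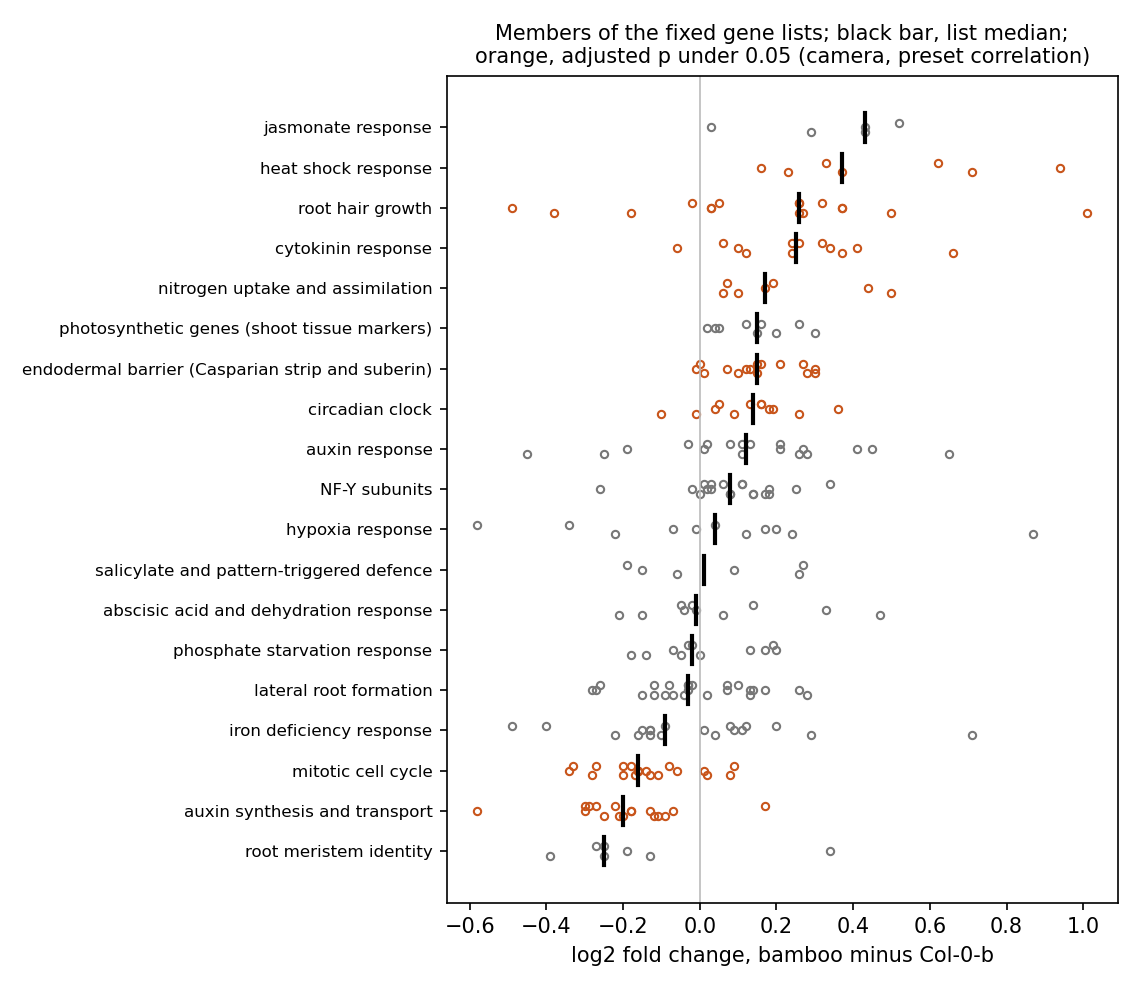
Log2 fold change, bamboo minus Col-0-b, of the tested members (circles) of the 19 gene lists, with the list median as a black bar and lists with a camera adjusted p under 0.05 in orange. The medians of the 8 lists in orange run from -0.20 (auxin synthesis and transport) to 0.37 (heat shock response), and most members lie within 0.50 of 0.

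Lateral root formation genes showed no shift as a list: 10 of 24 were higher and 14 lower, with a median of -0.03 (camera adjusted p = 0.762). LBD16 had a value of 0.17 and PUCHI -0.03. NF-Y subunits were higher in 17 of 19 members, with a median of 0.08 and an adjusted p of 0.135. Without bamboo replicate 3 the NF-Y median was 0.15 (adjusted p = 0.0234), and without bamboo replicate 2 it turned to -0.02 (adjusted p = 0.901). Root meristem identity genes were lower in 6 of 7 (median -0.25, adjusted p = 0.0641), with PLT2 at -0.39, and passed without Col-0-b replicate 1 (0.0305) or bamboo replicate 3 (0.00698). Without bamboo replicate 2 their median was -0.07 (adjusted p = 0.774). Jasmonate response genes were higher in 5 of 5 (median 0.43, adjusted p = 0.0764), and passed without Col-0-b replicate 1 (0.0306) or bamboo replicate 3 (0.0423). Their median was 0.62 in bamboo replicate 2 and 0.08 in bamboo replicate 3, and the adjusted p was 0.518 without bamboo replicate 2. Markers of shoot tissue, the photosynthetic genes, had a positive log2 fold change in 9 of 9 (median 0.15, adjusted p = 0.271). Mean normalized counts of CAB1, RBCS1A, LHCB2.1 and LHCB3 were nonetheless lower in bamboo. Their spread in Col-0-b was wide (CAB1 211 ± 209, against 180 ± 38.5 in bamboo). Without Col-0-b replicate 1 the photosynthetic genes had an adjusted p of 1.92e-06 and a median of 0.37. The list's median turned to -0.03 (adjusted p = 0.8) without Col-0-b replicate 2 and to -0.08 (adjusted p = 0.891) without Col-0-b replicate 3.

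The remaining lists did not pass. Median log2 fold changes were -0.01 for abscisic acid and dehydration (adjusted p = 0.459), -0.09 for iron deficiency (0.459), 0.01 for salicylate and pattern-triggered defence (0.552), 0.04 for hypoxia (0.632) and -0.02 for phosphate starvation (0.632). The test pointed down for hypoxia although its median and mean (0.04) were above 0, and up for the abscisic acid and phosphate lists although their medians were below 0. The iron deficiency list passed as lower without bamboo replicate 2 (median -0.08, adjusted p = 0.0107) and had a median of 0.12 without bamboo replicate 3 (adjusted p = 0.624). The salicylate list passed as higher without bamboo replicate 3 (median 0.32, adjusted p = 0.0445), and its median was 0 without bamboo replicate 2 (adjusted p = 0.199). COR47, a dehydrin, had a value of 0.47 and was the 1 member of the abscisic acid list called when adjusted over the list alone, and SUS1 was the 1 called member of the hypoxia list. Of the 7 long non-coding RNAs with known roles, 3 were measured, too few for a list test, and none was called.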

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

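Of these tests, DESeq2 was chosen after seeing the data. The counts of 14 genes higher and 13 lower in bamboo stayed within 1.5 times with a pseudocount of 8, TMM-rescaled values and edgeR on the recovered reads (15 higher and 13 lower, all 27 shared, with AT1G02540 added). They rose to 46 and 29 with no low-value filter, which tests more genes, and to 182 and 135 with DESeq2. DESeq2 kept 16 of the 27 genes and gave no adjusted p for the other 11. A log2 fold change of at least 1 left 5 and 5. Leaving out 1 library gave 6 to 894 genes higher and 4 to 1052 lower; the highest counts came without bamboo replicate 3, where the lone bamboo library is assumed to vary like the Col-0-b libraries. The same assumption is made without bamboo replicate 2, where the counts were far lower, so it does not by itself set the highest counts apart. Bamboo replicate 2, the library left in the setting with the highest counts, also stood apart on the first principal component (34.7, against 6.5 for bamboo replicate 3). The cause of these differences in counts was not tested. No called gene changed direction in any of the 11 alternatives; without Col-0-b replicate 1, 2 and 3, 19, 5 and 17 calls were lost, and without bamboo replicate 2 and 3, 8 and 1. The number of gene lists past the threshold, 8, fell to 0 with an estimated correlation (smallest adjusted p = 0.382) and ran from 5 to 12 when 1 library was left out, 5 being without bamboo replicate 2. Only 2 replicate numbers are shared by the genotypes. The differences between those numbers correlated at 0.08 across genes, and with a replicate block 513 genes were higher, 379 lower and 10 lists passed: root hair growth dropped out (adjusted p = 0.181, median 0.13) while root meristem identity (0.0136), jasmonate response (0.0394) and the photosynthetic genes (6.1e-06) came in. Col-0-b replicate 1 has no bamboo library with its number, so under the block it does not enter the fold changes. List medians were therefore those without Col-0-b replicate 1 (root hair growth 0.13, photosynthetic genes 0.37), and the same 10 lists passed in both settings. Without that library and with no block, 6 genes were higher and 4 lower. Under the block that library does not enter the spread of a gene either, which then rests on few libraries and on the trend shared over genes. Why more genes were called under the block was not tested. The alternatives planned for the HA-NF-YA2 line, its overlap with bamboo and its gene sets in bamboo were not run. Depth limits the low genes: 3 reads correspond to 2.54 to 3.7 normalized counts.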

Other observations

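The tests in this part were chosen after the results were seen, except the test of S-phase genes and the other splits of the libraries. The gene-list tests without bamboo replicate 2 had been chosen beforehand as alternatives, and only their use against an explanation, with its bounds, came after. Gene families were formed from shared symbol stems (194 families of at least 8 tested members), and 23 passed camera at the preset correlation, 13 higher and 10 lower in bamboo. Without bamboo replicate 2, 7 of the 23 still passed in the same direction; with an estimated correlation 0 passed (smallest adjusted p = 0.88). WRKY transcription factors were higher in 46 of 56 members (median 0.18, adjusted p = 9.4e-06, and 0.000451 without bamboo replicate 2), with WRKY25 at 0.38 and WRKY60 at 0.35. Beta-tubulin genes were lower in 9 of 9 members (median -0.20, adjusted p = 0.00309, and 0.00246 without bamboo replicate 2), with TUB1 and TUB7 both at -0.29. UMAMIT transporters, several of which export amino acids, were lower in 24 of 34 (median -0.16, adjusted p = 0.00152, and 2.15e-07 without bamboo replicate 2), with UMAMIT29 at -0.49 and UMAMIT14 at -0.41, but UMAMIT35 had 1.84. GSL callose synthases were lower in 8 of 9 (median -0.27, adjusted p = 0.00152, and 0.0392 without bamboo replicate 2), with GSL12 at -0.38. No member of these 4 families was called singly.

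Levels in CPM were also set against both wild-type sets, although these came with separate tables and may differ in other ways. For 13 of the 27 called genes both bamboo libraries lay outside the range of all 6 wild-type libraries, or 48.1%. Called genes all lie outside the Col-0-b range already, and of the 7015 tested genes that do so, 26.7% lay outside all 6. Called genes were also chosen by their gap to Col-0-b relative to the spread, which the 7015 were not, so these shares are not like for like. The Col-0 mean was nearer to bamboo than to Col-0-b (log2) for 16 of the 27. The matching share over other tested genes was not taken, so whether that count is high cannot be told. NRT2.6 was at a mean of 4.55 CPM in bamboo, 0.361 in Col-0-b and 0.135 in Col-0, and ARP9 at 16.4, 43.9 and 34.5. CBL8, which counts among the 13 by a narrow margin, was at 4.80, 1.45 and 4.30 (lowest bamboo library 4.77, highest Col-0 library 4.72), and CKX4 at 40.5, 25.9 and 40.0. HSP90.1 differed more between the wild-type sets (95.7 in Col-0-b and 11.2 in Col-0) than between bamboo (146) and Col-0-b. FRD3 was at 58.5 in bamboo, 81.2 in Col-0-b and 27.2 in Col-0.

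AT3G13276 and its neighbour AT3G13277 were both lower in bamboo. A drop of the whole stretch as large as that of AT3G13277 (-1.05) is argued against by the 10 nearest tested genes, whose median was -0.09. A smaller drop stays open. The genes on the side of VCR and PA200 were all lower (-0.28 to -0.07), and those on the other side ran from -0.10 to 0.09. Low levels of the pair may also occur in wild type: the highest Col-0 library reached 14% of the lowest Col-0-b library for AT3G13276, and 90.7% of the lowest bamboo library for AT3G13277. The tables were made apart, so whether wild type varies at the pair or the tables differ stays open. An effect of the change in BAMBOO on the pair stays open too and was not tested.

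AT5G35935 was higher and the adjacent AT5G35940 lower. A candidate explanation is that reads of one transcript were assigned to the other, since their sum changed by -0.17 (log2, SE 0.11). The reference shows no overlap of the 2 features. Called genes may also lie close together: 4 of the 27 lay within 20 features of another, against a mean of 0.808 in 10000 random draws (permutation p = 0.057). These 4 are the 2 pairs described here. AT5G35760, the called gene with the smallest adjusted p, has a locus number near those of AT5G35935 and AT5G35940 but lay outside that window. Whether called genes lie close together stays open. A change of the local sequence in bamboo was not tested.

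Small shifts of whole gene lists could come from bamboo replicate 2 alone. This is argued against where, without bamboo replicate 2, a list kept its call and a median more than 2 SE from 0, as the cytokinin (adjusted p = 4.95e-05), heat shock (1.37e-05) and auxin synthesis and transport lists (5.18e-06) did. It stays open for the endodermal (0.324), mitotic (0.128) and root hair lists (0.199), whose medians shrank, and, with less to suggest it, for the nitrogen (0.00237; median 0.25, SE 0.17) and clock lists (0.0552; 0.16, SE 0.08), whose medians did not shrink from 0.17 and 0.14. Less dividing tissue in the bamboo samples may go with the lower mitotic list: 15 S-phase genes outside that list had a median of -0.10 (SE 0.05; camera p = 0.0147, and p = 0.449 with an estimated correlation), at -0.16 in bamboo replicate 2 and -0.04 in bamboo replicate 3. Whether that reflects the change in BAMBOO or the tissue sampled was not tested.

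Regrouping the 5 libraries in all 10 ways into 2 and 3 gave 27 called genes for the real grouping, 1 of the 10, and at most 0 for the others (limma). With 10 splits a share under 0.05 cannot be reached.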
